A study of Mus musculus with 3 samples.

How the data were processed

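Strand-specific RNA libraries (KAPA kit) were made from total RNA of mouse primary cortical neurons in 3 groups, control, hypoxia and hypoxia with T3, with 1 library in each. Samples were placed in groups from the treatment labels, and the columns of the tables were matched to samples by the short names in the sample titles. The dose of T3 is stated in the labels. The submitters' processing notes list bcl2fastq 2.17, Bowtie2 2.1.0, RSEM 1.2.15 and the genome build mm10 without saying what each was used for. The authors deposited a table of 24054 genes whose values are CPM, read counts scaled to an effective library size, with TMM normalisation (trimmed mean of M-values) per the file name. The authors also deposited 2 tables, each of 13152 genes, that compare a hypoxic library with control. Their value columns hold the same reads on another scale and are treated as signal in the units of the deposited table, and are not used for folds here. Their fold column is, per the file headers and the values, a signed fold, written as minus the inverse where it is below 1. Per the file headers they also hold a p-value and a false discovery rate. The labels do not name the test, its assumed variability or the rule by which genes were kept, and none of these is assumed here.

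Every CPM value was a whole multiple, within 0.01, of the value of 1 read in its library, so that whole reads were recovered: 18081904 for control, 17118865 for hypoxia and 22533574 for hypoxia with T3. A read stood for 0.0463, 0.0552 and 0.0425 CPM, which implies effective library sizes larger than these read totals. The CPM sums were 837997, 945496 and 958205. A count of 0 allows up to 3 reads, or 0.139, 0.166 and 0.128 CPM. Sequenced reads without molecular identifiers are not independent molecules, so that intervals and floors cover counting error only.

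With 1 library per group no test across replicates exists, and the rule, the lists and the comparisons below were chosen before the data were examined. For each of 3 comparisons the log2 ratio of CPM was taken after adding 1 CPM, over 12692 genes with a mean over the libraries of at least 1 CPM, and genes at least 2-fold apart were counted. The printed folds are ratios of CPM without the added value. Their 95% intervals are exact Clopper-Pearson intervals on the share of the reads of a gene in 2 libraries. Genes were named by rule. Per comparison these were the 12 highest and the 12 lowest log2 ratios among genes with a mean of at least 5 CPM, up to 4 members of each gene list described with the largest ratios, and 19 genes fixed in advance. Some genes that this rule names are not reported here. The fixed genes were Vegfa, Slc2a1, Pdk1, Bnip3, Hif1a, Hr, Klf9, Dio3, Thra, Thrb, Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2, Tet3, Bcl2, Bax and Bdnf. Predicted models (symbols beginning with Gm or ending in Rik) stayed in the ranking and were only counted. Among the 12 on each side there was 1 higher and 1 lower model for hypoxia with T3 over control, 1 higher and 2 lower for hypoxia with T3 over hypoxia, and 0 for hypoxia over control.

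Gene lists, 38 in number, covered the responses to hypoxia, thyroid hormone and stress, apoptosis, DNA and histone methylation, neuronal function, metabolism and cell type markers. Some genes are on several lists, such as Gadd45b on those of DNA demethylation and immediate early genes, so the lists are not independent. For each list with at least 3 members compared, the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. These percentiles describe the libraries and are not p-values.

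The shared use of a library by 2 ratios was examined on the reads. In 100 simulations the reads were redrawn with no difference between libraries, and in 20 random splits genes were chosen on a random part of the hypoxia reads and measured on an equal remainder. The splits were repeated on 100 simulations in which the hypoxic libraries differed by counting noise alone. Genes were matched to GENCODE M21 (GRCm38, the same assembly as mm10) by symbol for 12121 genes and by synonym for 485 more, 99.3% of those compared, for coordinates, span, exonic length and GC content. Reads shared between copies were examined by the share of a gene's 31-base words that occur in transcripts of another gene, with 50% as the rule for a copy. This rule does not tell a separate near-identical gene from another annotation of the same locus. For genes with copies, the difference of the copies between the hypoxic libraries was set against that of the gene. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

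The procedure was tested on simulated data of 12692 genes with counting noise only. Of genes given a 2.5-fold difference, 92% of the higher and 84% of the lower were called, of those given a 4-fold difference 100% and 86%, and 0% of the unchanged genes. The intervals held the true fold in 95.6% of genes, 4% of 200 random lists fell beyond the central 95%, and a list of 20 raised genes stood at percentile 100. Alternatives were another pseudocount, filter, scaling, size rule or set of genes, the authors' deposited folds in place of the ratios, 5 expression bins, and, chosen after the data had been seen, an edgeR exact test with an assumed coefficient of variation, the removal of genes with copies, and random lists matched on gene span. Lists matched on gene span were not also matched on expression. None of the 13 mitochondrially encoded genes of the lists occurs in the table, and they were not analysed here.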

Results

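RNA was sequenced from primary cortical neurons, cells taken from the cerebral cortex of embryonic day 17 C57BL/6 mice and cultured for 7 days. There were 3 groups with 1 library each. The control culture was kept at 21% oxygen, the hypoxia culture was kept at 0.2% oxygen for 7 hours without added hormone, and the culture of hypoxia with T3 was kept at 0.2% oxygen for 7 hours with 5 nM triiodothyronine (T3), the active thyroid hormone. The labels do not state the hormone or serum content of the control medium. The deposited values correspond to 18081904 reads for control, 17118865 for hypoxia and 22533574 for hypoxia with T3, and 16927, 16886 and 17253 genes had at least 1 read. Because no group has a replicate, no difference below was tested against biological variation. Genes are described by their normalised read counts (CPM, scaled to library size), by folds of those values, and by exact 95% intervals that cover counting error only. Of 24054 genes, 12692 had a mean of at least 1 CPM and were compared under a rule of at least 2-fold on values with 1 CPM added.

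The libraries differed somewhat in composition. The ribosomal RNA gene Rn45s took 0.310% of reads in control, 0.541% in hypoxia and 0.903% in hypoxia with T3. All ribosomal protein genes together took 1.46%, 2.09% and 2.03%, and the 10 most abundant genes of each library took 4.58%, 5.16% and 5.45%.

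The comparison of hypoxia with control addresses what 7 hours of oxygen deprivation does to the transcripts of cultured neurons. Many of the highest ratios belonged to immediate early genes, transcription factors and effectors that neurons induce within minutes to hours of stimulation. Fos, a subunit of the AP-1 transcription factor, was at 15.6 CPM in control and 392 CPM in hypoxia, 25.2-fold higher (22.6 to 28.2). Classical targets of hypoxia-inducible factor (HIF) were higher as well: Slc2a1, the glucose transporter GLUT1, was at 8.06 and 51.1 CPM, 6.34-fold higher (5.39 to 7.50), and Vegfa, the angiogenic growth factor, at 47.0 and 147 CPM, 3.13-fold higher (2.91 to 3.37). Among the genes with the lowest ratios was Unc5c, a netrin receptor of axon guidance, at 75.9 and 13.8 CPM, 5.52-fold lower (4.83 to 6.33). Over all genes, 252 were at least 2-fold higher in hypoxia and 624 at least 2-fold lower.

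Among the immediate early genes, 25 of the 31 compared were at least 2-fold higher and none lower, with a median log2 ratio of 2.32 (percentile 100 among 10000 random lists of like expression). Fosb was at 2.13 and 91.9 CPM, 43.1-fold higher (32.2 to 59.1). Junb, another AP-1 subunit, was at 7.32 and 190 CPM, 25.9-fold higher (22.1 to 30.6). Arc, a regulator of AMPA receptor traffic at synapses, was at 1.30 and 31.2 CPM, 24-fold higher (16.4 to 36.5). Egr4, a zinc finger factor, was at 1.34 and 28.3 CPM and Klf4, a Krüppel-like factor, at 1.67 and 36.8 CPM. Outside the list, Cyr61, a secreted matricellular protein, was at 3.34 and 65.3 CPM, 19.6-fold higher (15.4 to 25.2), and Sertad1, a regulator of CDK4 and E2F activity, at 0.834 and 33.5 CPM. Amd1 and Tmem254b, which also rank among the 12 highest, have near-identical copies, and summed with these they were at 79.4 and 228 CPM and at 48.8 and 57.8 CPM. Bdnf, the activity-dependent neurotrophin on the same list, was at 17.2 and 18.9 CPM, 1.10-fold (0.943 to 1.27), a difference not detectable at this depth.

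Of the 33 HIF targets compared, 16 were at least 2-fold higher and none lower (median log2 0.83, percentile 100). Hk2, the hexokinase isoform induced by HIF, was at 2.97 and 36.2 CPM, 12.2-fold higher (9.43 to 16.0). Ankrd37, an ankyrin repeat gene, was at 0.371 and 6.08 CPM, and Ddit4, an inhibitor of mTORC1 signalling, at 56.9 and 242 CPM, 4.26-fold higher (4.0 to 4.54). Pdk1, which restrains pyruvate entry into the citric acid cycle, was 2.47-fold higher (2.28 to 2.68), and Bnip3, a mitophagy and cell death protein, 2.18-fold higher (2.02 to 2.37). The Hif1a transcript itself, whose protein is controlled mainly by degradation, was at 104 and 96.2 CPM. Of 18 glycolysis genes, 8 were at least 2-fold higher and all 18 had a ratio above 0 on the log2 scale (median 0.95, percentile 100). Ldha, which turns pyruvate into lactate, was at 230 and 610 CPM, 2.66-fold higher (2.57 to 2.75), and Pfkl, Slc2a3 and Tpi1 were 2.62-fold, 2.42-fold and 2.33-fold higher. The 33 nuclear genes of oxidative phosphorylation were all above 0 with none at 2-fold (median 0.49, percentile 100), and so were the 30 ribosomal protein genes (median 0.70, percentile 100).

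Stress pathways were higher in several lists. Some members of the integrated stress response list are on other lists too: Atf3 on that of immediate early genes, and Stc2 and Vldlr on that of HIF targets. In the integrated stress response, the programme that follows phosphorylation of eIF2α, 8 of 22 genes were at least 2-fold higher (median 0.59, percentile 100). Atf3, a stress-induced factor, was at 0.602 and 13.9 CPM, 23.1-fold higher (13.3 to 44.0), Ppp1r15a, the phosphatase subunit GADD34, at 20.5 and 188 CPM, 9.18-fold higher (8.31 to 10.2), and Cebpb at 4.50 and 35.8 CPM. Of 15 heat shock genes, 3 were at least 2-fold higher (median 0.50, percentile 99.9), led by the inducible chaperone Hspa1b at 7.88 and 42.0 CPM. Of 18 targets of p53, 5 were higher and 1 lower (median 0.28, percentile 96.7 by expression and 85.1 by gene span). Plk2 was at 135 and 506 CPM and Cdkn1a, the cell cycle inhibitor p21, at 27.8 and 86.1 CPM, while Rrm2b was 2.67-fold lower. Of 24 genes fixed for inflammation and interferon only 6 were compared, as the rest had a mean below 1 CPM. Of these 6, 3 were higher, namely Nfkbia, Nfkbiz and Irf1, at 3.50-fold, 4.09-fold and 4.08-fold. Of 19 unfolded protein response genes, 3 were higher (median 0.30, percentile 87.4), and of 16 NRF2 targets and metallothioneins, 1 was higher, the haem-degrading enzyme Hmox1 at 5.14 and 23.9 CPM (median 0.32, percentile 97.4 by expression and 94.4 by gene span).

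Genes that write, read and remove DNA methylation went in different directions. Of 13 genes of DNA demethylation, 3 were at least 2-fold higher and 1 lower (median 0.19, percentile 77.6). The higher members were the growth arrest genes Gadd45b, at 1.53 and 56.1 CPM, 36.7-fold higher (26.0 to 53.6), Gadd45g, at 3.75 and 63.9 CPM, and Gadd45a, at 1.2 and 7.62 CPM. The lower member was the dioxygenase Tet3, at 130 and 63.2 CPM, 2.06-fold lower (1.92 to 2.21). Its relatives Tet1 and Tet2 were 1.48-fold (1.35 to 1.64) and 1.23-fold (1.10 to 1.37) lower. Of 13 DNA methylation genes, 1 was at least 2-fold lower, the methyl-CpG reader Zbtb38, and none higher (median −0.11, percentile 14.9). The methyltransferase transcripts were 1.08-fold lower for Dnmt1 (1.02 to 1.14) and 1.25-fold lower for Dnmt3a (1.2 to 1.31), and for Dnmt3b, at 1.44 and 1.10 CPM, no difference was detectable at this depth. Among 16 histone demethylases the HIF target Kdm3a was 4.12-fold higher and the X-linked Kdm6a 3.57-fold lower. The median of that list, −0.23, stood at percentile 0.56 against lists of like expression and at 39.9 against lists of like gene span.

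Among 24 apoptosis-promoting genes, 2 were at least 2-fold higher, Pmaip1 and Bnip3, and none lower (median 0.20, percentile 95.8 by expression and 54.7 by gene span). Bax, a pore-forming member of the BCL-2 family, was 1.40-fold higher. Among 10 genes that oppose apoptosis, Mcl1 was 2.04-fold higher and Bcl2 2.33-fold lower (1.95 to 2.79), with a list median of −0.17 (percentile 6.79).

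Nckap5, the gene with the lowest ratio among those with a mean of at least 5 CPM, was at 23.9 and 1.88 CPM, 12.7-fold lower (8.98 to 18.6), and Maml2, a coactivator of Notch signalling, at 20.1 and 1.99 CPM, 10.1-fold lower (7.18 to 14.6). Chd7, the chromatin remodeller mutated in CHARGE syndrome, was 6.86-fold lower (5.52 to 8.60), Zswim6 6.96-fold, the repressor Trps1 7.59-fold, and the adhesion protein Cdh11 5.71-fold lower (4.97 to 6.59). Flrt2, Runx1t1, Tmem108 and Zfp462 were between 5.32-fold and 5.49-fold lower. Of 20 glutamate receptor genes, 1 was at least 2-fold lower, Grin2a, and of 14 GABA receptor genes, 3 were, among them Gabrb2, at 190 and 78.4 CPM, and Gabra4. Both list medians, −0.12 and −0.15, were low against lists of like expression (percentiles 3.47 and 3.46) but not against lists of like gene span (88.6 and 76.4). The 30 synaptic vesicle and scaffold genes held none at 2-fold (median 0.21, percentile 13.3 by expression and 100 by span). Lists of like span were not matched on expression, so the percentiles do not show which property accounts for a median.

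Markers of cell types differed in part. Summed over the oligodendrocyte markers, CPM was 367 in control and 219 in hypoxia, and 3 of 12 were at least 2-fold lower, the progenitor markers Pdgfra, Gpr17 and Olig2 (median −0.35, percentile 2.25). Inhibitory neuron markers summed to 422 and 583 CPM, with 11 of 12 above 0 (median 0.38, percentile 99.5 by expression and 91.9 by span). Of 14 general neuron markers, Nefl, the light neurofilament, was 2.27-fold higher and Tubb3, a neuronal tubulin, 2.03-fold lower (median 0.27, percentile 39.2 by expression and 100 by span). Of 12 excitatory neuron markers, Nrn1 was higher and 2 were lower, among them Bcl11b (median 0.07, below 0 with libraries scaled to equal sums, percentile 28.4). Astrocyte markers summed to 964 and 1015 CPM, with none of 11 at 2-fold (median 0.21, percentile 71.1). Among 11 neural progenitor markers, Hes5, a Notch effector, was 7.42-fold lower (median of the list 0.30, percentile 98 by expression and 63.4 by span).

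Gene length went with the ratio. Across genes, which are not independent replicates, the log2 ratio of hypoxia over control was lower the longer the span of the gene from first to last exon (Spearman's rho −0.507 over 12606 genes with an annotated span). The median span was 7.01 kb for genes at least 2-fold higher, 112 kb for genes at least 2-fold lower and 25 kb for the rest. Of the 1528 genes that span 100 to 300 kb, 275 were at least 2-fold lower and none higher, and of the 497 that span 300 kb or more, 78 were lower and none higher. Nckap5 (chromosome 1, 125913620 to 126830799, minus strand, mm10) spans 917 kb, while Fos (chromosome 12, 85473890 to 85477273, plus strand) is a short gene.

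**Figure D1:**
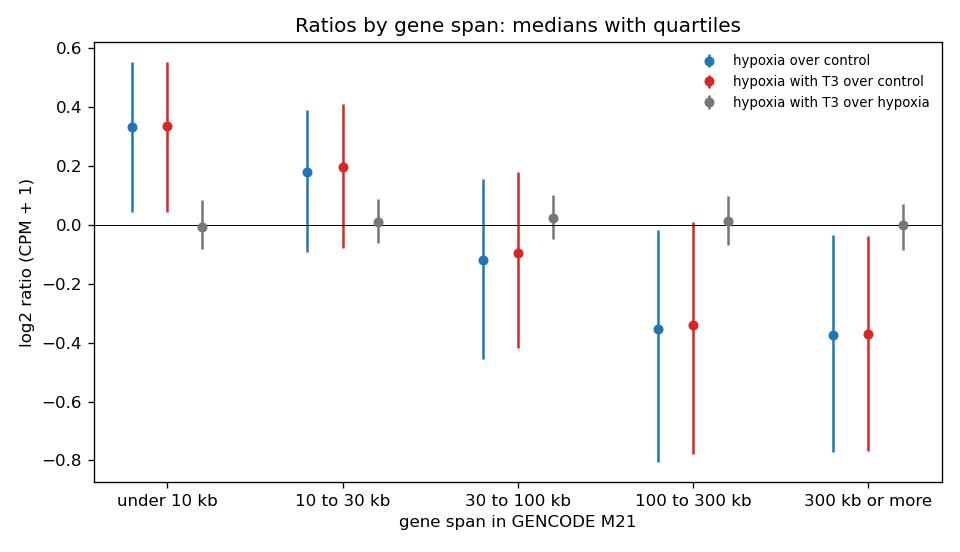
Median log2 ratio of genes (points) with the first and last quartile (lines) in classes of gene span, for hypoxia over control, hypoxia with T3 over control, and hypoxia with T3 over hypoxia. Against control the median went from 0.33 in genes under 10 kb to −0.37 in genes of 300 kb or more in both hypoxic libraries, and between the hypoxic libraries it stayed between −0.01 and 0.02.

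The split between higher and lower genes depends on the scaling: with each library scaled to the same sum, the median of all genes moved from 0.05 to −0.10 and the counts were 188 higher and 949 lower. In the authors' deposited table for this comparison, 85 of 13152 genes had a false discovery rate below 0.05, 51 higher and 34 lower, from a test that the labels do not name on 1 library against 1, and 75 of them were also at least 2-fold apart here. The authors' deposited table gave Fos a fold of 24.1 and a false discovery rate of 1.79e-07, Slc2a1 6.07 and 0.0165, Vegfa 3.0 and 0.401, and Nckap5 −13.2 and 9.37e-05, where a minus sign marks the inverse of a fold below 1.

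The comparison of hypoxia with T3 and hypoxia asks what the hormone adds under low oxygen, and it was the smallest of the 3. The clearest differences were in known thyroid hormone response genes. Hr, the corepressor hairless (chromosome 14, 70552212 to 70573548, plus strand), was at 4.75 CPM in hypoxia and 23.9 CPM in hypoxia with T3, 5.02-fold higher (4.0 to 6.38). Klf9, a Krüppel-like factor with a thyroid hormone response element (chromosome 19, 23141226 to 23168134, plus strand), was at 13.4 and 35.8 CPM, 2.68-fold higher (2.32 to 3.10). Only 16 genes were at least 2-fold higher with T3 and 8 at least 2-fold lower, and 99.0% of the genes compared were within 1.5-fold.

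Of 30 genes fixed as induced by thyroid hormone, 26 were compared. Of these, 4 were at least 2-fold higher with T3, none was lower, and 25 had a ratio above 0 (median 0.25, percentile 100). Beside Hr and Klf9 these were Sema7a, a membrane-anchored semaphorin, at 66.7 and 142 CPM, 2.14-fold higher (2.0 to 2.28), and Kcnj10, the glial potassium channel Kir4.1, at 17.4 and 36.1 CPM, 2.08-fold higher (1.82 to 2.37). Shh, the secreted morphogen, was at 6.08 and 11.4 CPM, 1.88-fold higher (1.5 to 2.36), and the clock-controlled factor Dbp at 1.60 and 3.83 CPM, 2.39-fold (1.56 to 3.77), short of the rule after 1 CPM was added. Dio3, which inactivates thyroid hormone, had 1 read in hypoxia and 19 in hypoxia with T3, a ratio of 14.6 with a counting interval from 2.33 to 608. Its mean was below 1 CPM, so it was not among the genes compared. Of 16 genes fixed as repressed by the hormone, the 11 compared had a median of −0.05 (percentile 6.22), with none at 2-fold. Among 18 genes of hormone transport, deiodination and receptors, none was at 2-fold (median −0.01). Thra, the main neuronal receptor gene, was at 642, 882 and 878 CPM in control, hypoxia and hypoxia with T3, and Thrb at 20.8, 5.19 and 5.10 CPM.

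Other genes at least 2-fold higher with T3 were Cyp26b1, which degrades retinoic acid, at 9.0 and 23.5 CPM, 2.61-fold higher (2.19 to 3.12), the tight junction protein Cldn12, 2.30-fold higher (2.08 to 2.56), the BH3-only protein Bcl2l11, also called BIM, at 9.39 and 22.2 CPM, 2.36-fold higher (1.98 to 2.83), and Mfap3l, 2.07-fold higher (1.82 to 2.36). Against control, with T3, Cyp26b1, Cldn12 and Bcl2l11 were 3.13-fold, 4.79-fold and 3.63-fold higher, but Mfap3l only 1.11-fold. Oxtr, the oxytocin receptor, and H2-T22 were also higher, by 1.12 and 1.10 on the log2 scale, and are named after their values were seen. Both had low values in control, hypoxia and hypoxia with T3. Oxtr was at 0.556, 1.49 and 4.42 CPM, and H2-T22 at 2.41, 0.994 and 3.27 CPM. H2-T22 also has 47.4% of its words in H2-T10, just short of the 50% rule for a copy, so its reads may not be assigned firmly. Among genes lower with T3 but short of the rule, Nyap2 was 1.89-fold lower (1.29 to 2.79), Ubald2 1.86-fold (1.55 to 2.23), the netrin receptor Unc5c 1.63-fold (1.35 to 1.98), and the synaptic adhesion gene Slitrk4 1.63-fold (1.42 to 1.86). Gfap, the astrocyte intermediate filament, was at 15.2, 23.7 and 13.9 CPM in control, hypoxia and hypoxia with T3.

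Several of the most extreme ratios between the hypoxic libraries were in genes with copies by the 50% rule, whose reads cannot be assigned firmly. Hr, also among the most extreme, had 0% of its words in another gene. Amd1, an enzyme of polyamine synthesis, had 0, 678 and 2 reads in control, hypoxia and hypoxia with T3, but shares 91.3% of its 31-base words with Amd2, and the sum of both was 79.4, 228 and 232 CPM. Eif3j2 was 3.60-fold higher with T3 and Eif3j1 2.15-fold lower, and their sum was 75.5 and 78.2 CPM in the hypoxic libraries. Snurf was 3.75-fold higher, and its words all lie in Snrpn as well, which may be shared annotation rather than a separate copy. The sum of both was 480 and 470 CPM. In Atp6v0c-ps2, Hmga1 and Moap1 between 73.3% and 92.9% of words lay in another gene. Without genes that have such copies by the 50% rule, 12 higher genes and 1 lower gene, Eif3j1, remained. Of the higher genes, 2 could not be matched to the annotation and examined. Another, H2-T22, had 47.4% of its words in H2-T10, just short of that rule. Eif3j1 is itself the copy of Eif3j2: it holds 94.0% of the words of Eif3j2, though only 41.0% of its own words lie there. Its lower value is thus not free of the same doubt.

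Outside the size rule, the immediate early genes were lower with T3 than without: 5 of 31 had a ratio above 0 on the log2 scale, with a median of −0.18 (percentile 0). Fosb was 1.40-fold lower (1.31 to 1.5), Klf4 1.62-fold (1.45 to 1.82), and Nr4a2, an orphan nuclear receptor, 1.32-fold (1.25 to 1.39). HIF targets had 24 of 33 above 0 (median 0.07, percentile 99.8), and p53 targets 13 of 18 (median 0.09, percentile 99.4). The integrated stress response (median −0.04, percentile 1.87) and ribosomal proteins (median −0.02, percentile 0.95) stood low by expression, and at percentiles 6.86 and 38.6 by gene span. Glycolysis, oxidative phosphorylation, heat shock, the unfolded protein response, NRF2 targets, histone demethylases, glutamate and GABA receptors, synaptic, neuron and excitatory neuron lists had medians from −0.02 to 0.03, with none at 2-fold. Of inflammation and interferon genes, 5 of 6 were above 0 (median 0.13, percentile 89.3), and of inhibitory neuron markers 3 of 12 (median −0.06, percentile 2.80).

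Among the DNA demethylation genes, Tet1 (chromosome 10, 62804570 to 62908996, minus strand) was at 35.6 CPM in hypoxia and 61.8 CPM with T3, 1.74-fold higher (1.58 to 1.91), with control at 52.9 CPM. Tet2 was 1.30-fold higher (1.17 to 1.44), with control at 38.7 CPM and hypoxia with T3 at 40.9 CPM. Tet3 was at 63.2 and 71.1 CPM, below control at 130 CPM. The list median was 0.07 (percentile 95.4), and that of the DNA methylation genes was 0.07 (percentile 94.0), with Dnmt3a 1.13-fold higher (1.08 to 1.19) and Dnmt1 at 113 and 111 CPM. Among apoptosis-promoting genes Bcl2l11 was the 1 gene at 2-fold (median 0.05, percentile 90.0), and Bmf, also a BH3-only gene, was 1.66-fold higher (1.15 to 2.42). Genes that oppose apoptosis had a median within 0.01 of 0 (percentile 31.9), with Bcl2 at 9.44 and 8.25 CPM.

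**Figure D2:**
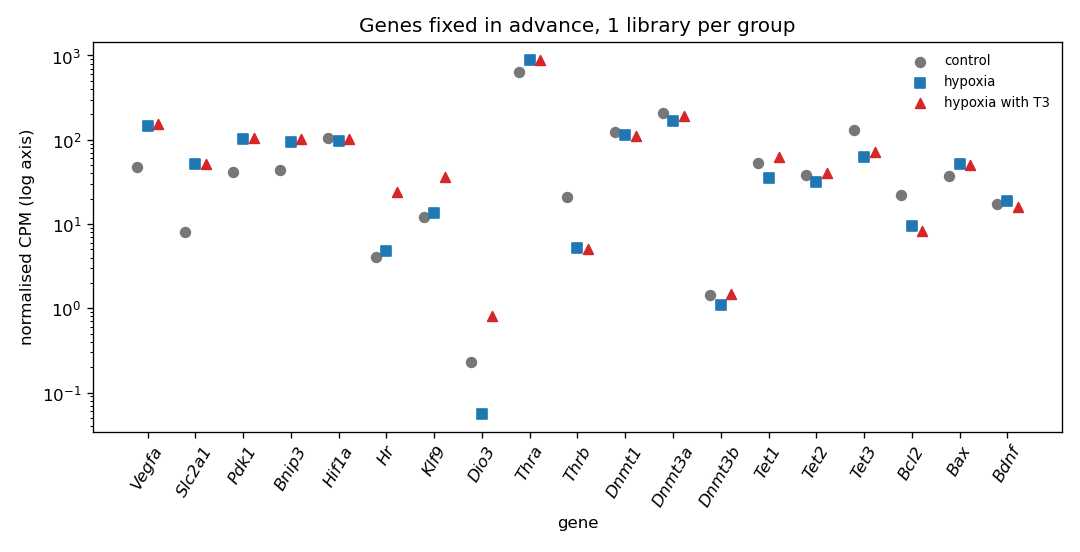
Normalised CPM (log axis) of 19 genes fixed in advance, with 1 point for each of the 3 libraries. Hr and Klf9 stand apart in hypoxia with T3 (23.9 and 35.8 CPM), whereas Slc2a1 and Vegfa are alike in both hypoxic libraries (51.1 and 51.7 CPM, and 147 and 155 CPM).

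**Figure D3:**
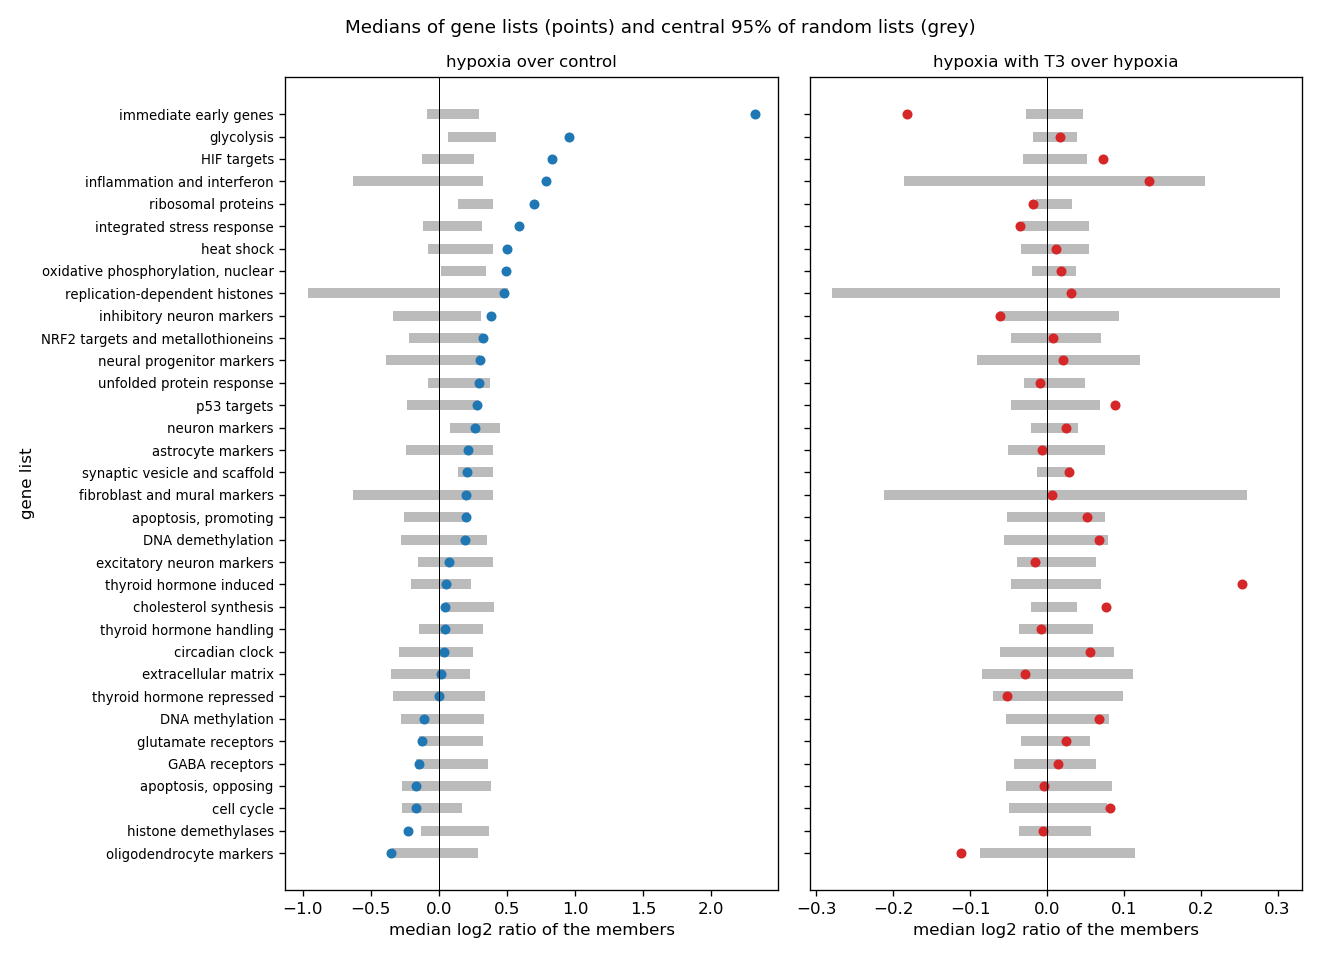
Median log2 ratio of each gene list (points) with the central 95% of medians of random lists of like expression (grey bars), for hypoxia over control on the left and hypoxia with T3 over hypoxia on the right, on different scales. Immediate early genes stand at 2.32 on the left and −0.18 on the right, and the genes induced by thyroid hormone at 0.05 on the left and 0.25 on the right.

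Genes at least 2-fold higher in hypoxia than in control had a median log2 ratio of −0.04 for hypoxia with T3 over hypoxia, with 97 of 252 above 0, and genes at least 2-fold lower had 0.05, with 393 of 624 above 0. The hypoxia library enters both ratios, so a part of a shift towards control arises by counting noise alone: 100 simulations with no difference between the hypoxic libraries gave −0.01 and 0.02. Relative to the median of all genes, the higher genes were at −0.0531, outside the simulated range of −0.0169 to 0.000827. The lower genes were at 0.0420, just above the simulated range of 0.00964 to 0.0410. When genes were chosen on a random part of the hypoxia reads and measured on the remainder, the medians were −0.03 (−0.04 to −0.02 over 20 splits) and 0.03 (0.03 to 0.04).

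The comparison of hypoxia with T3 and control describes the treated culture against the untreated culture at normal oxygen. The pattern was close to that of hypoxia alone, with higher values of Hr and Klf9 added. Gadd45b was 42.7-fold higher (30.3 to 62.2), Fosb 30.8-fold, Fos 22.8-fold, Junb 21.6-fold and Arc 22.0-fold. Hr was 5.92-fold higher (4.71 to 7.50), Klf9 2.99-fold (2.60 to 3.45), and Shh, which was already 6.55-fold higher in hypoxia without the hormone (4.05 to 11.1), 12.3-fold (7.80 to 20.5). In all, 262 genes were at least 2-fold higher and 582 at least 2-fold lower.

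Sertad1, Cyr61, Gadd45g and Arl4d, a small GTPase of the ARF family, were between 14.8-fold and 41.7-fold higher. Vegfa was at 155 CPM against 47.0 CPM and Slc2a1 at 51.7 CPM against 8.06 CPM. Of HIF targets 18 of 33 were at least 2-fold higher (median 1.10), of glycolysis genes 9 of 18 (median 1.0), and of immediate early genes 24 of 31 (median 2.36). Of the genes induced by thyroid hormone, 5 of 26 were at least 2-fold higher and 3 lower, the lower ones being Ntf3, Luzp1 and Thrsp (median 0.34, percentile 99.9). Tmem254b had 2 reads in control and 508 in hypoxia with T3, but all of its words lie in its copies and the sum of these was 48.8 and 58.5 CPM. Eif3j2 was 50.9-fold higher, against 58.3 and 78.2 CPM for its sum with Eif3j1.

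Among lower genes, Maml2 was 15.7-fold lower (10.9 to 23.6), Nckap5 13.4-fold (9.75 to 18.8), and Unc5c 9.01-fold (7.77 to 10.5). Zswim6, Chd7, Flrt2, Trps1, Runx1t1, the cadherin Cdh10 and the ciliary factor Rfx3 were between 4.94-fold and 7.72-fold lower. Oligodendrocyte markers had a median of −0.56 against control (percentile 0.11). Against hypoxia their median was −0.11 (percentile 0.81), but 5 of 12 were above 0 and their sum was 219 CPM in hypoxia and 222 CPM with T3. The ratio against control was again lower in longer genes (rho −0.499), whereas that between the hypoxic libraries had a rho of 0.0502.

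The 2 comparisons with control shared 216 higher and 483 lower genes. They also share the control library, whose counting noise alone correlates the ratios. The correlation across genes was 0.944, against 0.488 in 100 simulations without any difference. A correlation does not show the size of that noise. The covariance of the ratios was 0.306, against 0.00672 in the simulations. In every simulation 0 genes were at least 2-fold higher in both, and 0 at least 2-fold lower in both. These values argue against counting noise alone as the source of the overlap. Variation of the control culture beyond counting was not measured, so a part of the overlap that comes from that culture cannot be separated. With each library scaled to the same sum, the median of all genes moved from 0.08 to −0.10 and the counts were 196 higher and 898 lower. In the authors' deposited table for this comparison, 104 genes had a false discovery rate below 0.05, 53 higher and 51 lower, and 91 of them were at least 2-fold apart here. The authors' deposited table gave Hr a fold of 5.62 with a false discovery rate of 0.0295, Klf9 2.84 with 0.466, and Shh 11.6 with 0.000438.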

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

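Among the alternatives, the edgeR exact tests with an assumed variation, the removal of genes with near-identical copies and the lists matched on gene span were chosen after the data had been seen. No paired analysis was possible because each group has 1 library. In order, counts are given for hypoxia over control (252 higher, 624 lower), hypoxia with T3 over control (262 and 582) and hypoxia with T3 over hypoxia (16 and 8). A pseudocount of 5 CPM, which shrinks ratios of low values, gave 155 and 286, 167 and 269, and 8 and 1, and 0.1 CPM gave 44 and 18 for the last comparison. A mean of at least 10 CPM, which leaves fewer genes, gave 351, 322 and 3 lower genes. A rule of 1.5-fold gave 1074 and 1754, 1108 and 1663, and 91 and 35, and a rule of 3-fold gave 95 and 123, 101 and 130, and 5 and 3. Scaling to equal sums, which moves every ratio against control down, gave 949 and 898 lower genes in the comparisons with control. The authors' deposited folds gave 984 and 936 lower genes. They were taken without a pseudocount and differ from the ratios of CPM by a median of −0.061 and −0.072 on the log2 scale. Without genes with near-identical copies, 1 lower gene was left of 8 with T3 over hypoxia. The edgeR exact test (adjusted p below 0.05) with an assumed coefficient of variation of 0.2 gave 162 and 323, 173 and 336, and 5 and 5, and with 0.4 it gave 20 and 1, 19 and 7, and 2 and 2. That test applied no 2-fold rule, so its counts are not of the same kind as the others. They depend on an assumed variation that 1 library per group cannot measure. The other alternatives left each count within 1.5 times its value.

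The median log2 ratio of hypoxia with T3 over hypoxia among genes at least 2-fold higher in hypoxia, −0.043, was −0.071 with median-of-ratios scaling and −0.076 with equal sums. That among genes at least 2-fold lower, 0.052, was 0.085 and 0.021 with pseudocounts of 0.1 and 5 CPM, 0.033 with a mean of at least 10 CPM, 0.035 with median-of-ratios scaling and 0.034 with the split reads. No sign reversed under any of these alternatives.

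Of 181 gene ratios named and called at 2-fold, all 181 kept their sign under the other pseudocounts and scalings, and 181 stayed at 2-fold with a pseudocount of 0.1 CPM, 145 with 5 CPM, 176 with median-of-ratios scaling and 170 with equal sums. In the authors' deposited folds 165 of 167 did. The list medians of hypoxia over control for cholesterol synthesis, the genes induced by thyroid hormone, thyroid hormone handling, the circadian clock, extracellular matrix and excitatory neuron markers lie so near 0 that their sign differed under scaling to equal sums. With lists matched on gene span, 17 of the 102 percentiles moved into or out of the central 95%, and 85 did not. Depth limits genes under about 1 CPM most: Dio3 rests on 5, 1 and 19 reads.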

Other observations

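The test on the direction of copies, the simulations of the split reads with their settings and the percentiles by gene span were chosen only after the results had been seen.

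In the circadian clock list, 5 of 18 genes were at least 2-fold lower in hypoxia than in control and 1 higher (median 0.04, percentile 60): the core activator Arntl, also called Bmal1, was at 23.1, 9.67 and 14.5 CPM in control, hypoxia and hypoxia with T3, Npas2 was 2.80-fold lower in hypoxia, Rorb 2.38-fold and Hlf 2.64-fold, and the repressor Ciart was 4.74-fold higher. None of 31 cell cycle genes was at 2-fold, though their median of −0.17 stood at percentile 12.5 by expression and 0.03 by gene span, and between the hypoxic libraries 22 of 31 were above 0 (median 0.08, percentile 98.0). Mki67, a marker of cycling cells, was at 69.4, 34.8 and 41.8 CPM. Of 21 cholesterol synthesis genes none was at 2-fold (median 0.05, percentile 2.78 by expression and 13.2 by span), and 20 were above 0 with T3 over hypoxia (median 0.08, percentile 100). Extracellular matrix genes had none of 17 at 2-fold (median 0.01, percentile 64.1).

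Markers of microglia, vessels and blood had few reads. Microglia markers summed to 5.84, 9.50 and 11.4 CPM in control, hypoxia and hypoxia with T3, with 2 of them compared, of which the lysosomal protein Cd68 was 3.65-fold higher in hypoxia. Endothelial markers summed to 2.73, 3.59 and 3.57 CPM with 1 gene compared, and red cell markers to 1.76, 0.773 and 1.32 CPM with 0 compared. Fibroblast and mural markers summed to 28.2, 27.3 and 27.0 CPM (4 compared, median 0.20, percentile 85.5). Replication-dependent histones summed to 13.8, 20.8 and 23.4 CPM (3 compared, median 0.48, percentile 97.0 by expression and 68.3 by span). Of the 13 mitochondrially encoded genes 0 were in the table.

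The lower values of long genes were weighed against handling of the RNA. Loss of long transcripts by RNA breakage or size selection, as the whole cause, would leave no relation to gene span among transcripts of like length. Within 10 bins of exonic length the mean rho for hypoxia over control was −0.332. Exonic length here joins all annotated exons of a gene and is not the length of 1 transcript. The bins thus hold transcript length only roughly and cannot decide on such loss. GC content of the transcript, as the whole cause, is argued against by a mean rho of −0.448 within 10 GC bins. At least a part for both stays open, since the rho with span was −0.507 without bins. Within bins of span the ratio still had a mean rho of −0.131 with exonic length and 0.196 with GC content. Lower output of long transcription units under hypoxia, where elongation through a long gene would take a larger part of the 7 hours, predicted the same in the other hypoxic library, and the mean rho for hypoxia with T3 over control within exonic-length bins was −0.327. This may point to reduced elongation or initiation in long genes as a hypothesis, but both ratios use the same control library, so a feature of that library stays open. Loss of RNA in both hypoxic cultures would give the same result, so the prediction does not separate these explanations. The median log2 ratio of hypoxia over control was −0.119 at 30 to 100 kb and −0.354 at 100 to 300 kb. It was −0.374 at 300 kb or more, so a loss that keeps deepening with span was not clear in the longest genes.

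Differences of at least 2-fold between the hypoxic libraries fell into 2 parts. Of 22 such genes that could be examined, 11 have at least 50% of their words in another gene. The share was 1.0% of 997 genes drawn at random from those less than 2-fold apart, without matching on expression. In 11 of the 11 genes with copies, the copies differed in the direction opposite to the gene, by at least 0.5 of its own difference in 9. Reads divided differently between near-identical copies, or between annotations of the same locus, may therefore be the source for most of them. Examples are Amd1, at 37.4 and 0.085 CPM where its copy was at 191 and 231 CPM, and Eif3j2. For members of the thyroid hormone induced list at least 2-fold higher with T3 the same explanation is argued against, as 0 of 4 had such a copy and the highest share of words was 0.789%, in Kcnj10. An effect of the hormone and a difference between cultures both stay open for them, since each hypoxic group has 1 library.

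Genes at least 2-fold lower in hypoxia were slightly higher with T3, and genes at least 2-fold higher slightly lower, as a partial return towards control would give. With the genes chosen on 1 part of the hypoxia reads and measured on the rest, the median of the higher genes differed from that of all genes by −0.0428 on the log2 scale, below 100 simulations of counting noise of the hypoxia library in both ratios (−0.0105 to 0.00698) and below those under each of 4 other settings, which argues against such noise as the whole cause. For the lower genes the difference was 0.0222 (0.0148 to 0.0318 over 20 splits), above the simulated range of −0.0125 to 0.0149, but with a pseudocount of 5 CPM it was 0.00461 and with a mean of at least 10 CPM 0.0124, reached by 25 and 5 of the 100 simulations, so counting noise and a real shift cannot be told apart there. Splits and simulations treat reads as independent, so that noise from PCR copies of 1 molecule is not covered. Variation of the hypoxia culture beyond counting could also give the same shifts and was not measured, so that an effect of T3 and a difference between cultures both stay open for the higher genes.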
